A study of Mus musculus with 8 samples.

How the data were processed

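RNA from sorted mouse cells was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, which measure most genes through several probe sets spread over their exons. Per the labels, the cells were lineage-negative, Sca1-positive and cKit-positive, a gate that holds haematopoietic stem cells and early progenitors, and the RNA was amplified with the Ovation Pico system before biotin labelling. The 8 arrays fall into 3 groups: wild-type fetal liver (n = 3), Hmga2 knockout fetal liver (n = 3), both from embryonic day 14.5, and wild-type bone marrow of adults aged 8 to 12 weeks (n = 2). The labels name the samples of a group biological replicates. No scan date or batch was given in the sources used here.

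The deposited values are RMA intensities on a linear scale; RMA is named in the submitters' processing notes, and its version is not given in the sources used here. The deposited value table held 225993 probe sets with intensities from 3.03 to 13252, and a second deposited table held intensities of 199508 exon rows, of which 180224 carried the same 8 values as a probe set. The array medians lay between 6.20 and 6.27 on the log2 scale. No further normalization was applied, and all values were log2 transformed.

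Gene names came from the platform annotation. It gave exactly 1 gene symbol to 208881 probe sets, several to 1668 and none to 15444; only the first kind was used for genes. Of 19958 symbols, 17255 were current in the RefSeq table of assembly GRCm38.p6, 2585 were updated through a synonym and 118 were kept as given. The log2 values of all probe sets of a gene were averaged, with a median of 8 probe sets per gene. Averaging probe sets of different exons can hide changes limited to part of a transcript. Members of the gene lists without a value on these terms were not analysed here.

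The 3 pairs of groups were compared with limma (version 3.58.1, R 4.3.3), with lmFit and eBayes at default settings, 1 coefficient per group, all 8 arrays in 1 fit and two-sided p-values adjusted by the Benjamini-Hochberg method over all genes. Genes with an adjusted p under 0.05 were called. Fold changes are given with the moderated standard error (SE). With 3 or fewer arrays per group, the number of arrays limits the precision, and the p-values measure the spread between these samples.

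From gene lists fixed beforehand, 33 in number, those with at least 5 measured genes, 31 in all, were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry. Adjustment was over the lists of 1 comparison. Counts of called members are given over all genes and adjusted over the list alone. Olfactory receptor genes, 980 in number, served as a measure of background; this choice was made after seeing the data. Where the mean of the dimmer group lay below their 95th percentile, the fold is given as at least N-fold, with each of its arrays below the percentile raised to it, and log2 fold changes of such genes are measured differences with no order. No fold is given where both means lay below it. These bounds concern background alone and leave out sampling error, for which the SE is given beside many of them. They apply to the average over a gene's probe sets, and single probe sets can differ less between groups.

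The groups, gene lists, tests, the alternatives listed as planned and the rule for named genes were fixed before the data were examined. The rule took, per main comparison, the 10 largest changes in each direction among called genes whose arrays did not overlap between groups. Where fewer passed, it added up to 5 genes with the smallest p, named as not passing. It always took Hmga2, Lin28b, Igf2bp1, Igf2bp2, Igf2bp3, Arid3a, Kit and Ly6a, and up to 4 genes with the smallest p per list. Predicted gene models and small RNAs were counted but not named by its first part.

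The fit was tested on simulated arrays of 19958 genes with the measured means and the moderated spreads of the fit. For knockout against wild type, 17.5% of genes changed 1.5-fold were recovered, 75% of those changed 2-fold, 97.5% of those changed 3-fold and 100% of those changed 4-fold, with 8 false calls. For fetal against adult cells the shares were 0%, 52.5%, 95% and 100%, with 9 false calls. In each, the 1 list of 25 genes shifted by 0.3 on the log2 scale was found with no other list called. The simulated genes varied independently, so this check does not cover lists whose genes vary together. The estimated correlation of the G2 and M phase list, for example, was 0.349.

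The alternatives were the fit on 2 groups, the replicate number as a block, trended and robust variance, filters on dim genes and probe sets, medians of probe sets, single probe sets, quantile normalization, median centring, array weights, variance without moderation, the exon table, other thresholds, and each array left out in turn. Same-numbered samples were checked for shared deviations from their group means. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.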

Results

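Gene expression was measured in stem and progenitor cells sorted from fetal liver and adult bone marrow of mice, in 3 wild-type fetal, 3 Hmga2 knockout fetal and 2 wild-type adult samples. The series title names an axis of Lin28b, the let-7 microRNAs and Hmga2 in fetal blood stem cells. The comparisons ask what the loss of Hmga2 changes in fetal cells and how fetal cells differ from adult ones. Of 980 olfactory receptor genes, used as background, the median log2 intensity was 4.21 and the 95th percentile 5.97.

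Hmga2 encodes an architectural chromatin protein with AT-hook domains. Averaged over its probe sets, it fell at least 8.10-fold in knockout cells (measured log2 fold change -3.08, SE 0.19, adjusted p = 0.000448). On the log2 scale it went from 9.02 ± 0.21 (SD, n = 3) in wild-type fetal cells to 5.95 ± 0.12 (SD, n = 3). The wild-type arrays read 9.24, 9.01 and 8.83 and the knockout arrays 5.89, 5.88 and 6.08, so 1 of 3 knockout arrays lay above the background percentile. Igf2bp2, which encodes an mRNA-binding protein, fell from 8.41 ± 0.36 to 5.36 ± 0.12 (SD, n = 3 each). Its average over probe sets lay below the background percentile on every knockout array. The fall of that average is at least 5.44-fold (measured log2 fold change -3.05, SE 0.19, adjusted p = 0.000448). These were the 2 genes called by limma of 19958. No gene was called higher, while 709 were higher and 814 lower at an unadjusted p under 0.05.

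**Figure D1:**
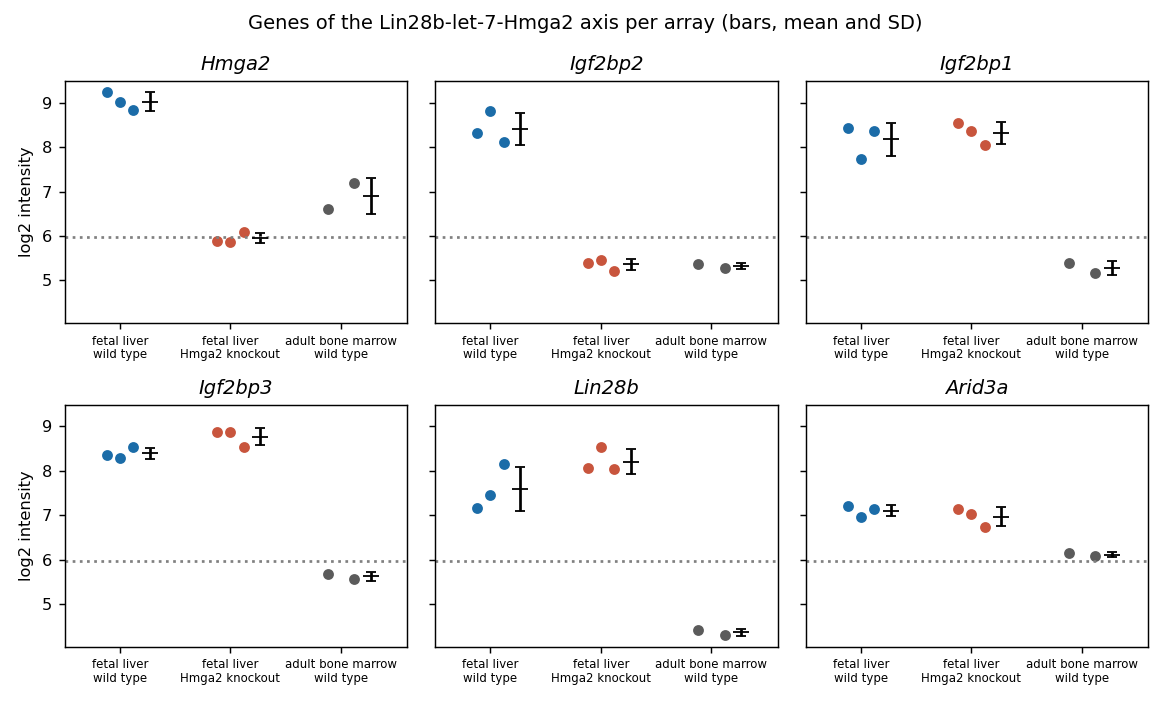
Log2 intensity of 6 genes in each array (points) with the group mean and SD (bars); the dotted line is the 95th percentile of olfactory receptor genes, 5.97. Hmga2 and Igf2bp2 are lower in all 3 knockout arrays than in any wild-type fetal array, and Igf2bp1, Igf2bp3 and Lin28b are higher in all 6 fetal arrays than in the 2 adult arrays.

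All 8 probe sets of Hmga2 were lower in knockout cells, by 0.69 to 6.78 on the log2 scale as group means differ, and 7 of them without overlap between arrays, which chance gives 1 in 10 times in either direction for 3 against 3 arrays. All 16 probe sets of Igf2bp2 were lower as well, with differences from -6.99 to -0.52, 13 without overlap. In knockout cells a probe set of Hmga2 still had a mean of 8.395 and one of Igf2bp2 7.707, above the background percentile. The folds given for both genes thus apply to averages and not to each probe set. The deleted part of Hmga2 is not given in the sources used here, so which of its probe sets lie inside the deletion was not tested. The call of Hmga2 ended when variances were not moderated (adjusted p = 0.209), in the exon table, which holds 2 rows of Hmga2 (adjusted p = 0.391), and when wild-type fetal arrays 1 and 2 were left out together (log2 fold change -2.88, adjusted p = 0.174). Over all alternatives its adjusted p ran from 0.000187 to 0.391. Igf2bp2 lost its call without moderation (adjusted p = 0.209) and without those 2 arrays (adjusted p = 0.0732).

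**Figure D2:**
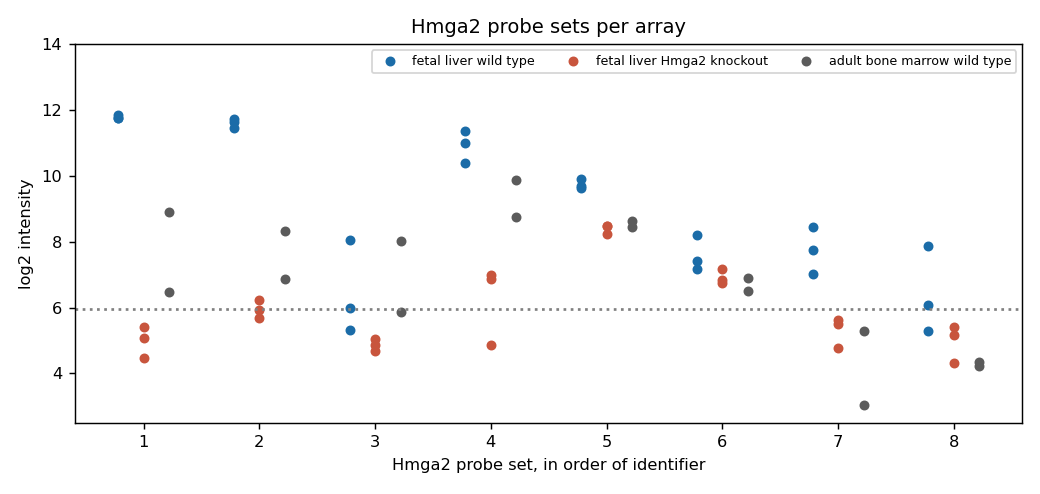
Log2 intensity of the 8 Hmga2 probe sets, in order of their identifiers, for each array; the dotted line is the 95th percentile of olfactory receptor genes. The knockout arrays lie below all wild-type fetal arrays in 7 probe sets, and the first shows a difference of 6.78 between the group means.

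The relatives of Igf2bp2 and the other genes of the axis gave no call in the knockout. Lin28b, an RNA-binding protein that blocks let-7 maturation, had a log2 fold change of 0.61 (SE 0.25, adjusted p = 0.632), Igf2bp3 0.38 (SE 0.155, adjusted p = 0.632), Igf2bp1 0.15 (SE 0.22, adjusted p = 0.866) and Arid3a -0.14 (SE 0.16, adjusted p = 0.834). Kit, which encodes a receptor of the sort gate, had -0.16 (SE 0.15, adjusted p = 0.798), and Ly6a, which encodes Sca1, -0.50 (SE 0.39, adjusted p = 0.750). Of genes not passing, 1700006J14Rik had the smallest adjusted p, 0.0504 (measured log2 fold change -1.37), but the rule leaves such symbols unnamed. Among genes open to naming, the smallest p-values not passing belonged to Derl2, Phf19, Ctns, Cd59a and Pdcl on the lower side. Their measured log2 fold changes ran from -1.66 for Cd59a to -1.05 for Derl2 (adjusted p = 0.155 for Derl2). On the higher side the smallest p-values belonged to Pwwp3b, Tspan5, Ccdc173, Zfp160 and Naa16, with 0.88 for Naa16 and 1.14 for Zfp160 (adjusted p = 0.292 for Pwwp3b). Phf19, Ctns and Cd59a lay below 5.97 in knockout cells, Ccdc173 and Zfp160 in wild-type cells and Pwwp3b in both. At an unadjusted p under 0.05 stood 1523 genes, where 997.9 are expected by chance. Single further calls came without wild-type replicate 3, Ctse (-3.41, adjusted p = 0.000509), and without knockout replicate 3, Sstr2 (2.10, adjusted p = 0.013). Others were Klri1 without the dimmest probe sets (adjusted p = 0.0312), which lay below 5.97 in both groups over all its probe sets, and 1700006J14Rik with array weights (adjusted p = 0.0264), at least 1.96-fold lower over all arrays. All 4 were chosen for naming after their values were seen.

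Among the fixed lists, the fetal stem cell genes were lower in knockout cells (median log2 fold change -0.17 over 16 genes, camera adjusted p = 0.0307; adjusted p = 0.653 with an estimated correlation). Of these 16, 2 fell over all genes, Hmga2 and Igf2bp2, and 5 were lower adjusted over the list alone. The other 3 were Dlk1, a Notch-family ligand (log2 fold change -0.69, SE 0.18), the growth factor gene Igf2 (-0.81, SE 0.24) and H19, an imprinted long noncoding RNA (-0.80, SE 0.26). None of these 3 passed over all genes. Without Hmga2 and Igf2bp2 the median of the list was -0.07 and its camera adjusted p 0.526, a check added after seeing the data. The list lost its call without wild-type replicate 3 (adjusted p = 0.118), without knockout replicate 1 (adjusted p = 0.196) and with the replicate block (adjusted p = 0.0858).

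The G2 and M phase genes were higher as a list (median 0.17 over 31 genes, 24 of them above 0, camera adjusted p = 0.0307; adjusted p = 0.690 with an estimated correlation), with 0 members called by limma over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. Prc1, which bundles microtubules of the spindle midzone, had 0.49, and Birc5, a chromosomal passenger protein, -0.38, neither passing. Fry gave an adjusted p of 0.00102 for the fetal stem cell genes and for the axis list, and 0.666 for the G2 and M phase genes. The fetal stem cell and axis lists both hold Hmga2, the gene knocked out, and Igf2bp2, their only members called over all genes. Fry was not run without them. The axis list did not pass with camera (adjusted p = 0.503), and its median of 0.10 and mean of -0.38 differed in sign, as did those of genes reported to respond to HMGA2 (0.07 and -0.18).

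The arrays of a group differed in the G2 and M phase list. Its mean per array, relative to all 8 arrays, was -0.03, 0.14 and 0.45 in wild-type replicates 1 to 3 and 0.48, 0.40 and 0.26 in knockout replicates 1 to 3. Against wild-type array 3 alone its median was -0.03. The list lost its call when any of wild-type replicates 1 and 2 or knockout replicates 1 and 2 was left out (adjusted p = 0.570, 0.0798, 0.302 and 0.106), after quantile normalization (adjusted p = 0.209) and without the dimmest genes (adjusted p = 0.108). Its median fell to 0.0675 without wild-type replicate 1 and lay between 0.134 and 0.180 in the other settings just named. Wild-type array 3 also stood apart in the hepatocyte list, with a mean of 0.29 against -0.13 to -0.03 in the other 5 fetal arrays. It had the lowest array weight, 0.555, which is measured against a group mean that arrays 1 and 2 also set. Without wild-type arrays 1 and 2 the hepatocyte list was lower in knockout cells (median -0.21, adjusted p = 0.00123). The imprinted genes had a median of -0.12 over 24 genes (camera adjusted p = 0.0623) and the S phase genes one of 0.13 over 27 genes (camera adjusted p = 0.128), neither passing. The imprinted list passed without wild-type replicate 1 (median -0.17, adjusted p = 0.0164) or knockout replicate 3 (median -0.20, adjusted p = 0.00991). It also passed without the dimmest genes (median -0.27, adjusted p = 0.00761). The S phase list passed without wild-type replicate 3 (median 0.23, adjusted p = 0.0488). Adjusted over their lists alone, the stem cell surface receptor gene Procr was higher (0.79, SE 0.18) and Myct1 lower (-1.16, SE 0.21) among haematopoietic stem cell genes; neither passed over all genes. Hoxa2 and Rhag also passed over their lists alone but lay below 5.97 in both groups, so no fold is given.

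Between wild-type fetal and adult cells 637 genes differed, 471 higher and 166 lower in fetal cells, and 458 of them at least 2-fold as measured. In 198 of them the mean of the dimmer group lay below 5.97, and in 25 of these both means did, so their log2 fold changes are measured differences with no order. Genes of the axis were higher in fetal cells. Lin28b was at least 3.09-fold higher (measured log2 fold change 3.23, SE 0.28, adjusted p = 0.0018), Igf2bp2 at least 5.44-fold (3.09, SE 0.22), Igf2bp1 at least 4.61-fold (2.89, SE 0.24) and Igf2bp3 at least 5.36-fold (2.77, SE 0.17, adjusted p = 0.000279), all 4 below 5.97 in adult cells. Hmga2 was 4.35-fold higher (2.12, SE 0.21, adjusted p = 0.00235), at 6.90 ± 0.41 (SD, n = 2) in adult cells, and the transcription factor gene Arid3a 1.98-fold (0.99, SE 0.18, adjusted p = 0.024).

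Other genes high in fetal cells were Stfa1, a cysteine protease inhibitor (3.71, SE 0.76), Cnn3, an actin-binding calponin (3.51, SE 0.31), H19 (3.05, SE 0.30), the actin-depolymerising factor Dstn (2.82, SE 0.27), Zfp711 (2.51, SE 0.36) and Prr11 (2.48, SE 0.27). On the adult side stood Mpa2l, of the guanylate-binding protein family (-5.02, SE 0.30), and Dntt, which adds nucleotides to rearranging antigen receptor genes (-4.77, SE 0.26, adjusted p = 0.000268). Also lower in fetal cells were Muc13 (-3.14, SE 0.30), the interferon-induced Ifi44 (-2.97, SE 0.25), Myl10 (-2.78, SE 0.44), H2-gs10 (-2.66, SE 0.31), the adhesion molecule gene Alcam (-2.61, SE 0.25), the platelet chemokine gene Pf4 (-2.59, SE 0.45), Cpne2 (-2.54, SE 0.32) and H2-Ab1, an MHC class II chain (-2.40, SE 0.28). The adult means of Stfa1, Cnn3, H19, Dstn and Zfp711 and the fetal means of Mpa2l, Dntt, Ifi44, Alcam, Pf4 and H2-Ab1 lay below 5.97. Against that level Dntt was at least 10.6-fold lower, Ifi44 5.56-fold, Alcam 5.27-fold, Pf4 4.36-fold, H2-Ab1 3.99-fold and Mpa2l 3.20-fold. On the same terms H19 was at least 7.26-fold higher, Dstn 6.0-fold, Stfa1 2.43-fold, Cnn3 1.83-fold and Zfp711 1.65-fold. Of the 20 genes that the rule for measured size took, 17 kept an adjusted p under 0.05 without each array in turn. Stfa1 lost it without fetal replicate 1 or 3 or either adult array (adjusted p up to 0.105). Pf4 lost it without fetal replicate 1 or 2 or either adult array (up to 0.0702), and Myl10 without adult replicate 1 (adjusted p = 0.0656). Arid3a lost it without fetal replicate 1 or 3 or either adult array (up to 0.0729). Of all 66 named genes called, 32 passed without each of the 5 arrays.

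Lists of G2 and M phase and of S phase genes were higher in fetal cells with camera, and the G2 and M phase list did not pass with an estimated correlation. All 31 G2 and M phase genes lay above 0 (median 1.03, camera adjusted p = 1.455e-20; adjusted p = 0.0775 with an estimated correlation). Over all genes 14 rose, and 23 adjusted over the list alone, among them the cyclin gene Ccna2 (1.72), Hmmr (1.53), Ube2c (1.47) and the checkpoint kinase gene Bub1 (1.45). Of 27 S phase genes (median 0.85, adjusted p = 0.0336 with an estimated correlation), 8 rose over all genes and 17 adjusted over the list alone, with the primase gene Prim1 at 1.82 and the ribonucleotide reductase genes Rrm1 at 1.21 and Rrm2 at 1.01. The G1 regulators gave no call as a list (median 0.01, camera adjusted p = 0.724), with Ccnd1 higher (1.46) and the CDK inhibitor gene Cdkn2c lower by at least 1.05-fold (measured -1.92, the fetal level below 5.97). In the wild-type fetal arrays 1 and 2 the mean of the G2 and M phase list, -0.03 and 0.14, lay below that of array 3, 0.45, and above those of adult cells, -1.07 and -0.62.

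Oxidative phosphorylation genes rose (median 0.65 over 27 genes, 26 of them above 0, adjusted p = 0.0336 with an estimated correlation), 5 of them over all genes and 20 adjusted over the list alone, with Sdhb at 1.17, Ndufv2 at 1.14 and Uqcrc1 at 1.11. For glycolysis genes the median was 0.34 over 17 genes (camera adjusted p = 0.0162; adjusted p = 0.230 with an estimated correlation), with 3 higher over all genes, Ldha (1.07), Aldoa (1.00) and Tpi1 (1.00), and 6 adjusted over the list alone. The list's call ended after quantile normalization (median 0.07, adjusted p = 0.366), without fetal replicate 1 (adjusted p = 0.0563) and without adult replicate 2 (median -0.06, adjusted p = 0.169). Quantile normalization also ended the calls of Sdhb, Ndufv2, Ldha, Aldoa and Tpi1 (adjusted p from 0.0588 for Sdhb to 0.224 for Tpi1), and those of Ndufb5 (0.0948) and, on other lists, Igf2 (0.0551), Egfl7 (0.0576), Ccnb2 (0.0588), Cd48 (0.0790) and Ireb2 (0.119). All of these stayed higher in fetal cells after it, with log2 fold changes from 0.54 for Ireb2 to 1.36 for Igf2. Igf2 was at 1.39 before it, while Tpi1 fell from 1.00 to 0.64.

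The axis list (median 0.76 over 13 genes, adjusted p = 0.0122 with an estimated correlation) had 6 genes higher over all genes and 7 adjusted over the list alone. Known let-7 targets were higher too (median 0.56 over 28 genes, adjusted p = 0.0107 with an estimated correlation), with 7 higher and 1 lower over all genes, and 13 higher and 1 lower adjusted over the list alone. The 1 lower was Thbs1, a matricellular protein gene also on the platelet list, by at least 1.57-fold (measured -1.10, SE 0.17, the fetal level below 5.97). All 16 fetal stem cell genes lay above 0 (median 1.11, adjusted p = 0.0072 with an estimated correlation), 9 of them higher over all genes and 13 adjusted over the list alone. The 9 were Lin28b, Hmga2, Igf2bp1, Igf2bp2, Igf2bp3 and Arid3a, also on the axis list, and H19, Dlk1 and Igf2, also on the imprinted list. The lists of this paragraph thus share genes and are not independent results. The imprinted genes had a median of 0.32 over 24 genes (camera adjusted p = 0.000463; adjusted p = 0.112 with an estimated correlation), with 4 higher over all genes, H19, Dlk1 (1.06), Igf2 (1.39) and the CDK inhibitor gene Cdkn1c (0.83), and 8 adjusted over the list alone.

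Interferon response genes were lower in fetal than in adult cells in all 29 members (median -0.84, adjusted p = 0.00729 with an estimated correlation), 9 over all genes and 20 adjusted over the list alone. Called members besides Ifi44 included Ifit3 (-1.78, SE 0.21), Oas2 (-1.60, SE 0.28) and Iigp1 (-1.59, SE 0.15). Their fetal means lay below 5.97, which leaves at least 2.30-fold for Ifit3, 2.90-fold for Oas2 and 1.82-fold for Iigp1. MHC class I and II genes were lower in all 17 members (median -0.88, adjusted p = 0.0072 with an estimated correlation), 7 over all genes and 14 adjusted over the list alone, with H2-Aa at -2.34 (at least 3.69-fold, the fetal level below 5.97), H2-K1 at -1.64 and H2-D1 at -1.59. Immediate-early and stress genes had a median of -0.71 over 25 genes (camera adjusted p = 1.457e-09; adjusted p = 0.0806 with an estimated correlation), 4 lower over all genes, Fosb (-2.18), Dusp1 (-2.08), Nr4a1 (-1.53) and Egr1 (-0.93), and 12 adjusted over the list alone.

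**Figure D3:**
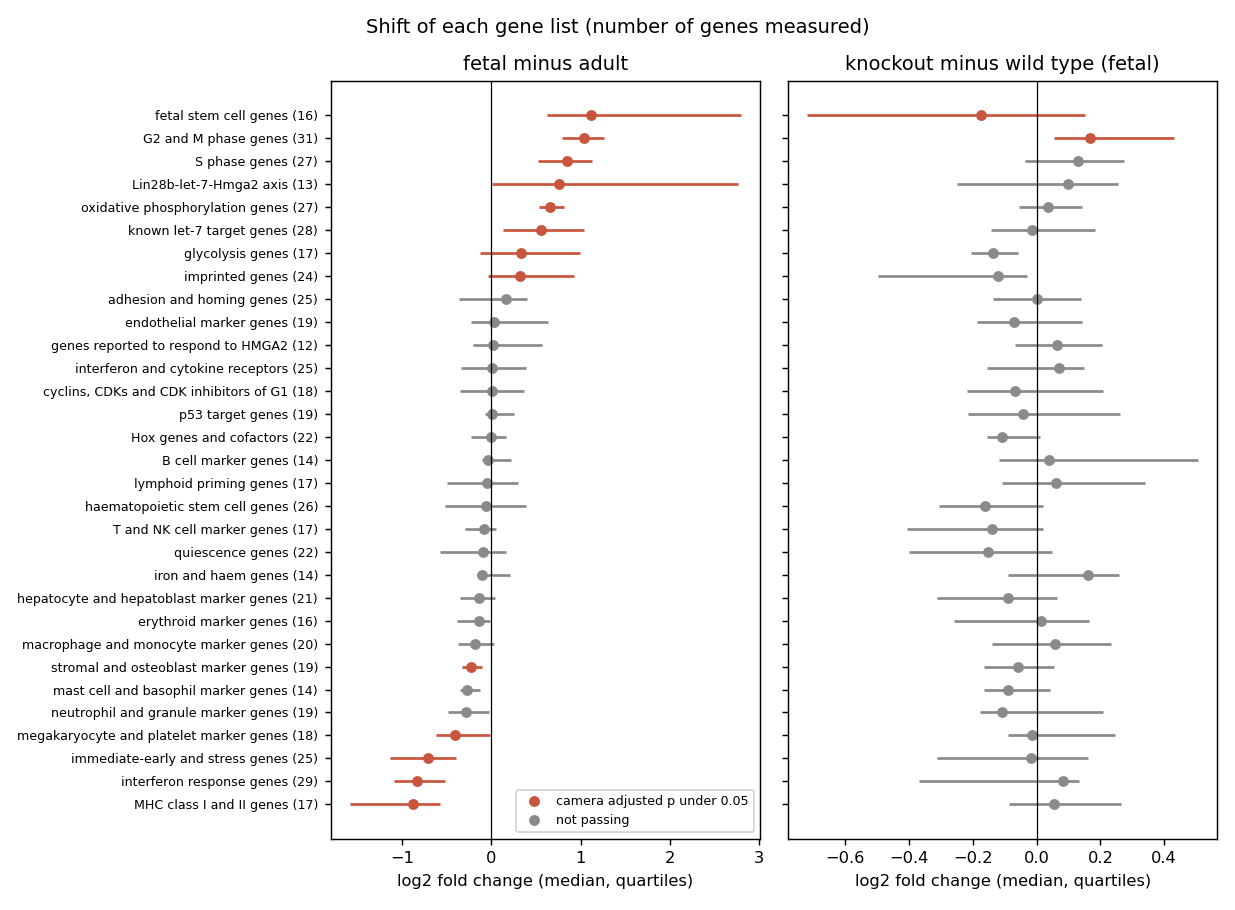
Median log2 fold change of the members of 31 gene lists (points) with quartiles (lines), for fetal minus adult and knockout minus wild type; the number of genes measured follows each name and the x axes differ. The G2 and M phase list has a median of 1.03 in the first and 0.17 in the second, and the interferon list -0.84 in the first.

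**Figure D4:**
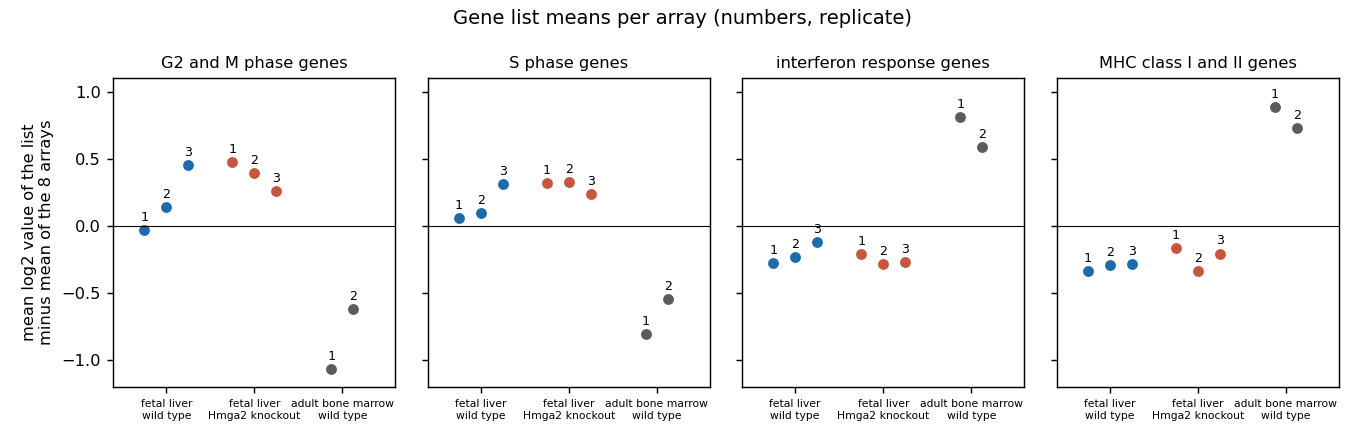
Mean log2 value of 4 lists in each array relative to the mean of the 8 arrays, with the replicate number above each point. The G2 and M phase list lies at -0.03 and 0.14 in wild-type fetal arrays 1 and 2 and at 0.26 to 0.48 in the other fetal arrays.

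Megakaryocyte and platelet markers were lower in fetal cells (median -0.41 over 18 genes, camera adjusted p = 0.00127; adjusted p = 0.0654 with an estimated correlation), 3 over all genes, Pf4, Thbs1 and the integrin gene Itga2b (-0.75), and 4 adjusted over the list alone. Stromal and osteoblast markers had a median of -0.23 over 19 genes (camera adjusted p = 0.00764; adjusted p = 0.244 with an estimated correlation) and 0 members called by limma over all genes or the list alone, with 4 lower at an unadjusted p under 0.05. That list's call ended after quantile normalization (adjusted p = 0.0539) and without adult replicate 1 (adjusted p = 0.0569). The remaining 18 lists gave no call with camera, with medians between -0.29 for neutrophil markers and 0.17 for adhesion genes. Neutrophil markers passed without fetal replicate 3 (adjusted p = 0.0126) or adult replicate 2 (adjusted p = 0.00515) and with the replicate block (adjusted p = 0.0332). Macrophage and hepatocyte markers passed without fetal replicate 3 (adjusted p = 0.0411 for each), and hepatocyte markers without the dimmest genes (adjusted p = 0.0415). After quantile normalization quiescence genes (adjusted p = 0.00149) and cytokine receptors (adjusted p = 0.0397) passed, and genes reported to respond to HMGA2 did without fetal replicate 2 (adjusted p = 0.0346). With fry, genes reported to respond to HMGA2 (adjusted p = 0.0232), p53 targets (adjusted p = 0.0372) and erythroid markers (adjusted p = 0.0447) passed. Their medians were 0.01, 0.01 and -0.14. Called genes among the 18 lists included Ctnnal1 (1.67), Cxcr4 (-0.83), Cd48 (1.19), Egfl7 (1.30), Plk2 (1.71) and Ireb2 (0.79). Others had a dimmer group below 5.97: Bank1 was at least 1.43-fold higher, and Il1r1 at least 2.96-fold, Ctsg, a granule protease, 1.48-fold, Il18r1 1.18-fold and Ptpn21 1.18-fold lower. Ly6a, a gene of the sort gate, was at -1.82 (SE 0.44, adjusted p = 0.0592) and Kit at -0.28 (SE 0.17, adjusted p = 0.411), neither passing. The share of higher calls was 73.94% here, 52.03% after quantile normalization and 80.82% after median centring. Without wild-type fetal arrays 1 and 2 all 66 named genes called kept their direction. That was fixed beforehand, since in all 637 called genes the fetal arrays did not overlap with the adult arrays. The count of called genes without 1 array was 360, 287 and 225 for fetal replicates 1 to 3, and 373 and 574 for adult replicates 1 and 2.

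Lin28b (log2 fold change 3.84), Igf2bp3 (3.15) and Igf2bp1 (3.04) were higher in knockout fetal than in adult cells, and Dntt (-5.14), Mpa2l (-4.48) and Ifi44 (-2.97 in wild-type and -3.07 in knockout cells) lower. Averaged over its probe sets, Hmga2 was at least 1.86-fold lower in knockout than in adult cells (measured -0.95, adjusted p = 0.0291). Its probe sets did not all differ that way. The probe set with the largest fall in the knockout read 4.991 in knockout and 7.687 in adult cells. Another read 8.395 and 8.529, and a further one was higher in knockout cells, at 5.29 and 4.166. Igf2bp2 lay below 5.97 in both groups. Adult levels of the 3 higher genes and knockout levels of the 3 lower ones were below 5.97 on every array, so these 6 values are measured differences with no order. All 31 G2 and M phase genes lay above 0 (median 1.18, adjusted p = 0.0988 with an estimated correlation) and all 17 MHC genes below 0 (median -0.84, adjusted p = 0.025 with an estimated correlation). In all, 1779 genes differed, 1158 higher and 621 lower in knockout cells. In 684 of them, 219 higher and 465 lower in knockout cells, the mean of the dimmer group lay below 5.97. In 272 of these both means did. The higher share was 65.09%, 50.89% after quantile normalization and 77.33% after median centring. Without a knockout array the count was 616, 482 and 602 for replicates 1 to 3, and without adult replicate 1 it was 553. Of genes called in both comparisons with adult cells, 412 were higher in each (27.3 in independent lists) and 137 lower in each (5.2 in independent lists); 100 simulations of unchanged groups sharing arrays gave a mean of 0. With no effects nearly no gene is called, so that 0 says little about the shared arrays. Part of the excess may come from the shared adult arrays. The 471 genes higher in fetal cells had a median knockout minus wild-type difference of -0.01, and the 166 lower ones of 0.06.

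Whether knockout cells moved toward adult cells was measured across all genes as the correlation of the knockout difference with the adult difference, both taken against wild-type fetal cells. The covariance was -0.0032, where 100 simulations of unchanged groups sharing the wild-type arrays gave 0.0244, a difference of -0.0275. The simulated genes varied independently, so the simulation holds no shift of whole arrays. Wild-type fetal arrays 1 and 2 lay nearer to the adult arrays than the other fetal arrays, which by itself lowers the covariance. The difference thus cannot tell a move of knockout cells from the place of these arrays. The correlation was -0.02 against a simulated mean of 0.447, from 0.427 to 0.469, but the simulation also leaves adult cells unchanged, so the correlations are not comparable in size. With disjoint wild-type arrays the correlation was -0.16 on average, from -0.306 to 0.0824 over the 3 ways. Genes are not independent replicates, so no p-value belongs to these values. Without wild-type fetal arrays 1 and 2 the correlation was 0.422, against only 1 wild-type array. Sharing that array alone gives a positive correlation, and no simulation was run for this setting.

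The fetal samples also differed in ways that the groups do not explain. Over the 1779 genes that separate knockout from adult cells, with 0 for the knockout mean and 1 for the adult mean, wild-type fetal arrays 1 to 3 lay at 0.304, 0.28 and 0.0715. The first principal component held 43.2% of the variance. Wild-type replicates 1 and 2 had both Xist, at 10.1 and 8.67, and the Y-linked Kdm5d, at 7.08 and 7.92, while knockout replicate 2 had Kdm5d at 8.21 and Xist at 3.62 and the other arrays had Xist from 10.2 to 11.1 and Kdm5d from 4.27 to 4.85.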

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

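Among the tests in this part, those on wild-type arrays 1 and 2 for the G2 and M phase list, mature immune cells, probes that fit a strain badly, handling of the adult tissue and adult cells mixed into samples were chosen after the result was seen.

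Data outside the gene comparisons held signals. Of 17112 probe sets without exactly 1 gene symbol, 1 was lower in knockout cells, and of 19284 exon rows found in the exon table alone, 1 was lower in knockout cells and 49 differed between fetal and adult cells, 33 of them higher in fetal cells. These rows carry no gene name here.

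The count of 2 genes in the knockout comparison was set against the other ways to split the 6 fetal arrays. Of 10 splits, 1, the real one, gave as many genes, and the highest of the others gave 1. With 10 splits no share under 0.05 can be reached.

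The G2 and M phase list was higher in knockout cells (camera adjusted p = 0.0307; adjusted p = 0.690 with an estimated correlation). With the Y-linked genes as covariate the median was 0.1538, near the 0.166 without it (camera adjusted p = 0.0471, and 0.710 with an estimated correlation). That argues against sex composition as the whole cause only as far as a linear Y-linked level measures it. Wild-type arrays 1 and 2 carried both Xist and Y-linked signal, which such a level may not capture. The place of wild-type arrays 1 and 2 is a candidate explanation: against wild-type array 3 alone the median was -0.0275 (SE 0.0392, over genes of 1 array), and against arrays 1 and 2 it was 0.4088. Array 3 stood apart in the hepatocyte list, with a mean of 0.29 against -0.13 to -0.03 in the other 5 fetal arrays. Its array weight, 0.555, was the lowest, but weights rest on distance from a group mean that arrays 1 and 2 also set. Over all genes array 3 correlated with the knockout arrays at 0.9739 to 0.975, and arrays 1 and 2 at 0.9523 to 0.9626. Likeness to knockout arrays does not decide which wild-type arrays are typical, so that stays open. A difference in cycling between genotypes was not tested apart from these arrays.

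Interferon and MHC lists were higher in adult cells, and age and tissue stay open as biological explanations, untested. Single probe sets that fit a strain badly are argued against: 82.03% of the probe sets of the 29 interferon genes and 90.67% of those of the 17 MHC genes were lower in fetal cells against 50.78% of all probe sets (medians per gene 90.91%, 100% and, over all genes, 55.2%), but strains that differ along whole MHC genes were not tested. Mature immune cells in the sort stay open, though the lineage gate would remove them: of 70 markers in 4 lists 47 lay below 5.97 in both groups, and over the 20 with a mean above it the smallest distance of a list from the interferon or MHC list was 0.252 standard errors, for neutrophils without adult replicate 2. Lyz2 was at 7.18 in fetal and 7.15 in adult cells, a level that would hide a small share. Handling of adult tissue could also have raised immediate-early genes, whose list median was -0.7083, but a tissue difference allows the same. Handling and tissue cannot be told apart, since bone marrow is 1 group and both fetal groups are liver.

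Wild-type fetal arrays 1 and 2 lay nearer to the adult arrays than the other fetal arrays. Adult cells in these samples as the whole cause are argued against: 14 genes seen in adult but not in knockout cells gave adult RNA shares of 3.81% (SE 2.26) and 5.43% (SE 2.22), while 732 genes higher in knockout than in adult cells would need 45.1% (SE 1.79) and 37.8% (SE 1.60), at least 11.83 standard errors more, with SEs over genes. The distribution of values is argued against as the whole cause by their mean position after quantile normalization, 0.2461 against 0.2921. Array 3 moved the other way, from 0.0715 to 0.094, so the distance between them narrowed and a partial role of the distribution stays open. Sex stays open: the position without X and Y genes was 0.2954, but the 68 genes left out carry 6.19% of its weight, so leaving them out could not decide, and effects on other chromosomes were not tested. The design names no biological difference between replicates, and none was tested.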

How the results depend on the processing

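Added after seeing the data were the fits without wild-type fetal arrays 1 and 2, the Y-linked covariate, lists without Hmga2 and Igf2bp2, and list tests without each array and after rescaling. Counts are for knockout, fetal against adult, and knockout against adult cells (2, 637 and 1779 genes); other counts stayed within 1.5 times. Signal over background limits dim genes, as olfactory receptor genes reach 5.97 at their 95th percentile.

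With the replicate number as a block the counts were 2, 185 and 489, and lists called in the knockout 1 (fetal stem cell genes lost, adjusted p = 0.0858). The numbers do not pair the samples: same-numbered wild-type and knockout deviations correlated at -0.0132, 0.0179 and -0.0164, wild-type fetal and adult ones at 0.1124 and 0.0452, and knockout and adult ones at -0.038 and -0.0287. Fitting 2 groups gave 120 genes for fetal against adult cells and 1732 for knockout against adult cells. Medians of probe sets gave 179 and 762, single probe sets 0, 30 and 178, variance without moderation 0, 50 and 116, and the exon rows 1 (Igf2bp2), 322 and 1103. There were 1293 and 3597 genes at an adjusted p under 0.10, and 1067 for knockout against adult cells after quantile normalization. Without wild-type fetal arrays 1 and 2 the counts were 0 and 89, with the lone sample assumed to vary like the other groups; with the covariate, 283 for fetal against adult cells. Where limma called 0 genes in the knockout, 14792 of 208881 single probe sets and 1364 of 19958 genes without moderation had an unadjusted p under 0.05. By chance a share of 0.05 is expected, which is 997.9 of the genes. Without the 2 arrays fewer genes than that had such a p. Leaving out each array gave 2 to 3, 225 to 574 and 482 to 1253 genes. The cause was not tested.

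Hmga2 lost its call without moderation (-3.0758, adjusted p = 0.209), in the exon table (-3.1195, adjusted p = 0.391) and without wild-type fetal arrays 1 and 2 (-2.8765, adjusted p = 0.174), and kept it without each array (-3.1754 to -2.9677).

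The correlation of -0.0243 changed sign or moved under the block (0.0414), without the dimmest genes (0.0028 for the smaller filter, 0.0353 for the larger, at 50 percent), with medians of probe sets (0.0416), quantile normalization (0.049), array weights (0.0086), the exon table (0.0296), disjoint arrays (-0.1602) and without wild-type fetal arrays 1 and 2 (0.422), and ran from -0.0725 to 0.101 without each array. It counts as moved where its sign changed or it shifted by more than 0.0635, the SD of its values without each array, a rule set after the values were seen. The correlation on 2 groups only was not run, since it needs 3 groups.

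Lists called in the knockout numbered 0 with an estimated correlation, 1 after quantile normalization, 1 without Hmga2 and Igf2bp2, and 0 to 3 without each array; for fetal against adult cells 7 with an estimated correlation and 12 to 16 without each array. The G2 and M phase list turned to -0.0275 without wild-type fetal arrays 1 and 2 (adjusted p = 0.584). For the 123 named genes of the fetal and adult comparison, 367 values under alternatives lost the call, 22 gained it and 0 reversed; for the 122 of the knockout comparison besides Hmga2, 2 lost it, both of Igf2bp2, 0 reversed and 21 of genes not passing changed sign.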

Other observations

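Socs7, Gid4, Dusp22 and Hdac9 below were chosen for naming after their values were seen, and the test of the let-7 list was set before its result was seen.

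Of 471 genes higher in fetal cells, 16 moved at least 50 percent of the way to the adult level in the knockout and 9 moved as far away from it. The first include Hmga2, Igf2bp2, Dlk1, Igf2, Socs7, Gid4 and Dusp22, of which Hmga2 and Igf2bp2 passed over all genes. Of 166 genes lower in fetal cells, 8 moved toward the adult level by that much and 0 away, among them Il1r1 (measured 1.17) and Hdac9 (measured 0.53), neither passing and both below 5.97 in wild-type cells. The genes were taken by the same wild-type arrays that the moves are measured against, which by itself favours moves toward the adult level, and no value without effects was computed.

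The let-7 target list holds the axis genes, so its shift in fetal cells might rest on them, which is a hypothesis. Without the axis genes the 17 remaining targets had a median of 0.3991 against 0.5608 for the whole list (camera adjusted p = 0.0109; adjusted p = 0.133 with an estimated correlation), which argues against the axis genes as the whole cause at the preset correlation alone. Of the 17, Ccnd1 was higher (1.46, SE 0.18) and Thbs1 lower by at least 1.57-fold (measured -1.10, SE 0.17).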
